A study of Mus musculus with 12 samples.

How the data were processed

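RNA was measured in 12 libraries from mice of a mixed 129 and C57BL/6 background that carry an active Notch1 intracellular domain in adipocytes. WAT stands for white adipose tissue (4 libraries, from animals 3 weeks of age) and LPS for liposarcoma (8 libraries, from animals 9 to 12 months of age). Per the labels, total RNA from frozen tissue was depleted of ribosomal RNA and made into stranded libraries, so transcripts without a poly(A) tail, such as histone mRNAs, can be counted. The labels call the libraries biological replicates. Age and tissue change together between the groups, so no comparison between WAT and LPS parts one from the other.

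The deposited table gives FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per gene locus and library. Per the submitters' processing notes, the tools were Trimmomatic, Bowtie2, TopHat2 2.1.0, Cufflinks 2.2.1 and Cuffdiff 2.2.1 on build GRCm38, with no role or order stated. Whether the authors scaled the deposited FPKM further between libraries is not given in the sources used here. Some loci that overlap share 1 row: 828 rows join several gene names. Such rows were counted in tests across the table, but they were not used for gene lists or named genes, a choice made after the table was seen. Of the rows with a single name, 33939 lay at an overlapping locus of the same name in GENCODE M21, which is on GRCm38, and 15700 of those had identical ends once the table's starts were counted from 1. Coordinates are given in that form. Reads shared by near-identical copies (histone genes, ribosomal pseudogenes) may be split by such tools, so values of those genes are uncertain. A listed 0 can be a failed estimate, since rows of several small nucleolar RNAs alternate between 0 and high values.

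Fragment totals are not part of the table. FPKM sums ran from 771665 to 996090 per library. Depth was approached through the low values: over 922 single-transcript genes longer than 2000 bases, the 5th percentile of the non-zero products of FPKM and length stood for the value of about 1 fragment. By that measure WAT 1 was the deepest library, at 2.74 times the depth of LPS 1, the shallowest, and LPS 5 lay at 1.39 times. For a transcript of 2 kb, 1 fragment was worth 0.0164 FPKM in WAT 1 and 0.0448 FPKM in LPS 1. No counts were recovered, and no counting interval is given.

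The main comparison used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), two-sided, with trend and robust empirical Bayes and Benjamini-Hochberg adjustment at 0.05. Rows with at least 1 FPKM in at least 4 of the 12 libraries were tested. No covariate or block entered the fit. A log2 difference on this scale understates the change of genes near or below 1 FPKM. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 40 lists that had at least 5 tested members. The lists (44 in all, 773 genes), the main tests and the alternatives were fixed before the data were examined, apart from the additions named here and in the closing section. Age was tested within LPS as a log2 slope per month in limma, over rows with at least 1 FPKM in at least 4 of the 8 libraries. A list score was the mean, over the list's genes, of log2 values standardised across the 8 LPS libraries. Relations between scores were tested with exact permutation of all 40320 pairings, two-sided, over a family of 7. The limma fit was tested on simulated data made from the real means and spreads: with 14821 genes it recovered 92% and 94% of genes changed by log2 -2 and 2, and 54% and 62% of those changed by log2 -1 and 1, with 6 false calls. With 13280 genes the age fit recovered 86% and 88% of slopes of log2 -1 and 1 per month, with 14 false calls. In both simulations the changed genes were drawn only from the more abundant ones, and noise was independent between genes. Recovery of genes near 1 FPKM, false calls among correlated genes and recovery of smaller slopes were therefore not tested.

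Named genes followed a rule fixed beforehand: Notch1 and 4 of its targets; the 10 largest differences each way among called genes whose groups do not overlap; from each list the 2 largest called members each way and the most abundant member not called; and 12 genes of adipocyte or tumour interest. Members of the lists could be left out, and some genes that the rule names are not reported here. Hey2, Ccnd1, Abcc9, Cspg4, Mcam, Acta2, Pecam1, Kdr, Cd248, Fabp4, Cd36, Slc2a4, Tusc5, Ttn, Igf2, Pdgfra, H19, Meg3, Rian, Mirg, Actb, Krt19, Upk1b, the mitochondrial rows, Gm10800, the sex-linked genes and the genes that open the closing observations were added after their values were seen.

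Alternatives fixed beforehand were other pseudocounts, filters and scalings, array quality weights, an exact permutation test per gene and a replicate block. Also fixed were the Xist level as a covariate, plain empirical Bayes, a test against a log2 difference of 1, and leaving out each library. Added after the data were seen were fits without joined and small RNA rows, without the WAT libraries richest in muscle transcripts (WAT 1 and WAT 4), and without these and LPS 5. Ranges of adjusted p over alternatives leave out the test against 1 for genes and the estimated correlation for lists, which ask other questions. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.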

Results

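The series compares tumours with the fat tissue they are held to arise from. Ad/NICD mice express the Notch1 intracellular domain, the active form of the receptor, in adipocytes, and develop liposarcomas, malignant tumours of the fat lineage. The data are FPKM values of 12 ribosomal RNA-depleted libraries: 4 of white adipose tissue (WAT) from animals 3 weeks old and 8 of liposarcoma (LPS) from animals 9 to 12 months old. The number of rows at or above 1 FPKM lay between 12965 (LPS 5) and 14248 (WAT 4). LPS 5 stood apart: the predicted gene Gm10800 reached 361556 FPKM there, against at most 3340 FPKM in the other libraries, and 754 of 1408 olfactory and vomeronasal receptor genes were above 0, against 63 to 160 elsewhere. Rows of LPS 5 had a median ratio of 0.814 to their geometric mean over the libraries, against 0.991 to 1.06 in the others. Most of its genes thus read low as deposited, and the main fit did not rescale them.

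**Figure D1:**
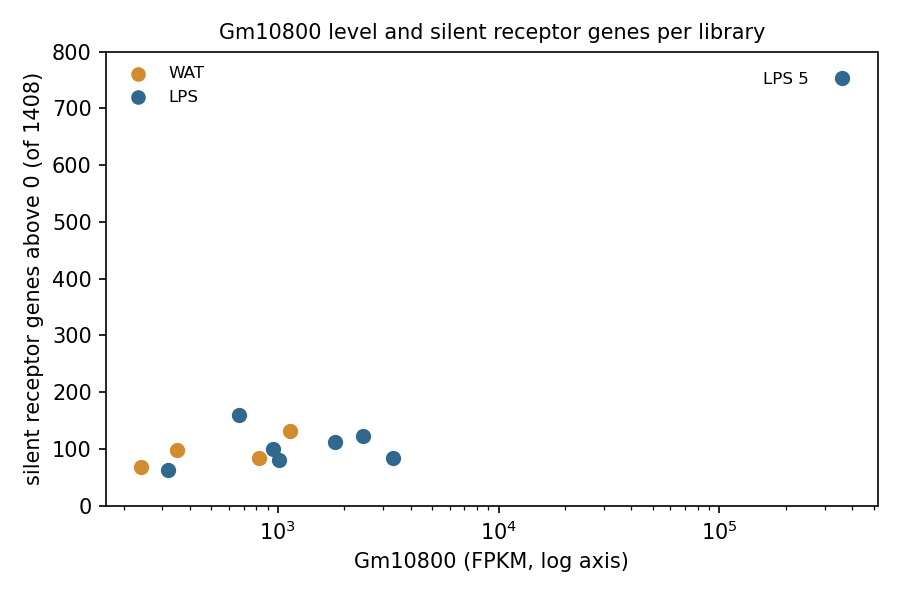
Number of olfactory and vomeronasal receptor genes above 0 FPKM (vertical axis, of 1408) against the level of Gm10800 in FPKM (horizontal log axis), 1 point per library. LPS 5 lies alone at 754 genes, and the other 11 libraries lie between 63 and 160.

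The comparison asks which transcripts part established tumours from young fat that carries the same transgene. The genes with the largest falls in LPS belong to adipocytes, and among the fixed lists that of pericytes, the cells that wrap small vessels, had the highest median. Of 14821 rows tested, 2806 were higher and 4007 lower in LPS (limma, adjusted p below 0.05), of which 1324 and 2315 differed by at least 1 on the log2 scale. In 4838 rows (32.6%) all LPS libraries lay on one side of all WAT libraries, and chance gives 0.404%. The balance depended on scaling and on the filter. Of the calls, 58.8% were lower as deposited and 45.2% after quantile normalization, which moved the median of all rows from -0.05 to 0.10. With no filter on low values, 67.1% of calls were lower. The first principal component held 59.0% of the variance and parted the groups. The second held 9.90% and set LPS 1, LPS 3 and LPS 7 (-47.8, -54.0 and -28.2) apart from the other LPS libraries (5.11 to 42.0).

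**Figure D2:**
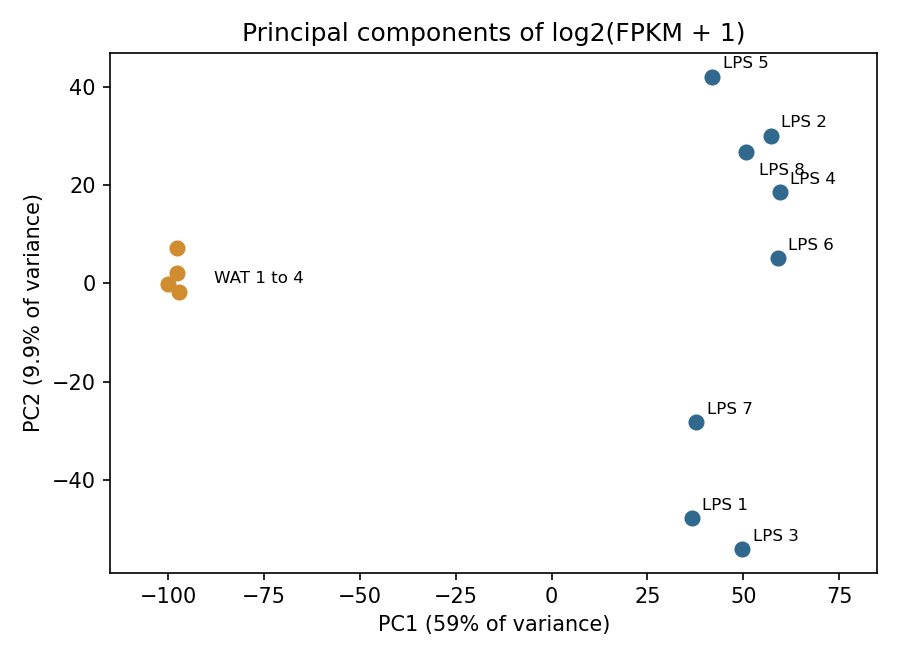
First and second principal components of log2(FPKM + 1) over the tested rows, 1 point per library, axes in component scores with the percent of variance each holds. The WAT libraries lie together at the left, and the LPS libraries spread along the second component from -54.0 (LPS 3) to 42.0 (LPS 5).

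The 10 genes with the largest higher level in LPS among those without overlap were Higd1b, Rps3a3, Hist1h2al, Rgs4, Kcnj8, Ndufa4l2, Rgs5, Cox4i2, Olfr558 and Pla1a. Higd1b led with 2.34 ± 0.585 FPKM in WAT (SD, n = 4) and 322 ± 237 FPKM in LPS (SD, n = 8), a log2 difference of 6.30 ± 0.48 (SE). Rgs4 went from 5.09 to 309 FPKM and Cox4i2, a subunit of cytochrome c oxidase, from 4.64 to 216 FPKM. Rps3a3 and Hist1h2al have near-identical copies in the genome, and their values are uncertain. The 10 largest in the other direction were Cfd, Pck1, Car3, Gpd1, Ucp1, Thrsp, Cox8b, Retn, Adipoq and Dgat2, all genes of white or brown adipocytes. Cfd, the adipokine adipsin, went from 2667 ± 417 to 4.06 ± 9.37 FPKM, a log2 difference of -10.08 ± 0.66. The LPS mean of Cfd rests on LPS 5, at 27.2 FPKM, and the other 7 tumours were at most 1.29 FPKM.

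Of the 40 lists tested, 8 were called higher and 8 lower at the preset correlation, and with an estimated correlation only the mature adipocyte and the thermogenic lists passed. fry called 10 lists up and 15 down. Of the lists called by camera, fry did not call replication-dependent histones (fry adjusted p = 0.117) and macrophage markers (fry adjusted p = 0.155). The number of called lists did not stand out among splits of the 12 libraries into 4 and 8. Of 100 splits, the real one included, 36 called at least 16 lists. No such split divides the WAT libraries evenly, so part of the difference between LPS and WAT stays in the splits. They therefore cannot decide whether the number of lists exceeds chance. Counts adjusted over the list alone are given where they differ from those over all rows, and the others were the same.

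**Figure D3:**
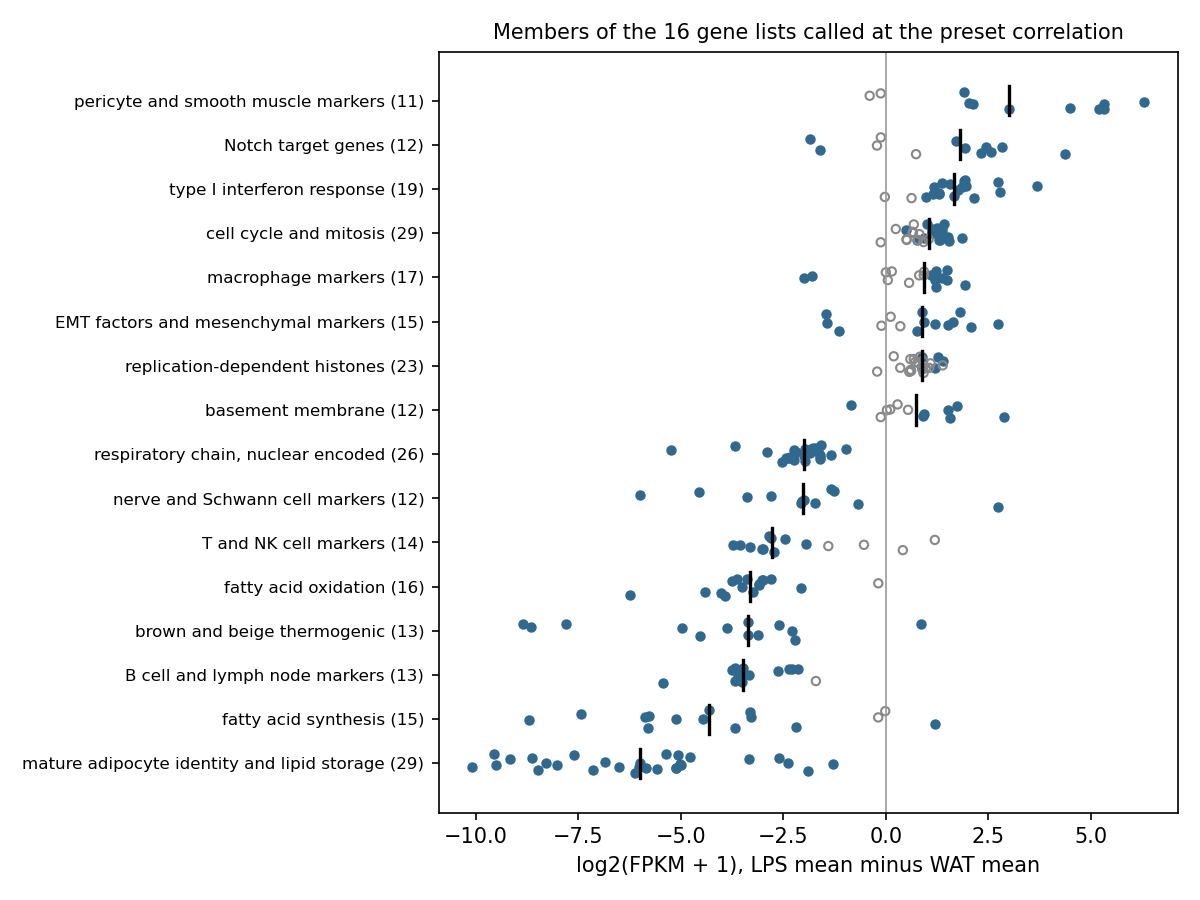
Log2 difference (LPS mean minus WAT mean of log2(FPKM + 1), horizontal axis) of each tested member of the 16 lists called at the preset correlation, with the number of tested members in brackets. Filled points passed adjusted p of 0.05, open points did not, and the vertical bars are medians, from -5.99 for the mature adipocyte list to 3.02 for pericyte and smooth muscle markers.

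The adipocyte programme was lost in the tumours. All 29 tested members of the mature adipocyte list were lower, with a median log2 difference of -5.99 (camera adjusted p = 8.83e-21; adjusted p = 0.0138 with an estimated correlation). Adipoq, the adipokine adiponectin (chromosome 16, 23146536 to 23158028), fell from 586 ± 50.7 FPKM in WAT (SD, n = 4) to 0.936 ± 1.43 FPKM in LPS (SD, n = 8), with a limma adjusted p = 1.30e-09. LPS 5 held 4.26 FPKM of Adipoq and the other 7 tumours at most 1.6 FPKM. Plin1, the coat protein of lipid droplets, fell from 454 ± 35.2 to 4.70 ± 11.1 FPKM, and LPS 1 held 32.2 FPKM of it. Cebpa, a transcription factor of adipocyte differentiation, fell from 177 ± 10.7 to 4.77 ± 2.49 FPKM (adjusted p = 2.43e-08). Pparg, the master regulator of fat cell fate (chromosome 6, 115361221 to 115490401), was uneven: 70.4 to 134 FPKM in WAT, and 82.2, 94.2 and 66.5 FPKM in LPS 1, LPS 3 and LPS 7 against 2.93 to 16.4 FPKM in the other 5 tumours. Its log2 difference of -2.38 ± 0.88 passed narrowly (adjusted p = 0.0413). Leaving out WAT 1, WAT 2, WAT 3 or WAT 4 ended the call for Pparg (limma adjusted p = 0.0846, 0.0631, 0.0771 and 0.102), as did leaving out LPS 2, LPS 4, LPS 5, LPS 6 or LPS 8 (adjusted p = 0.0643, 0.0663, 0.0639, 0.0630 and 0.0591). Over the alternatives other than the test against a difference of 1, its adjusted p ran from 0.00668 to 0.288. Fabp4, a lipid carrier that PPARG activates, followed the same libraries, with 2000, 1229 and 1070 FPKM in LPS 1, LPS 3 and LPS 7 and 66.4 to 135 FPKM in the other tumours.

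**Figure D4:**
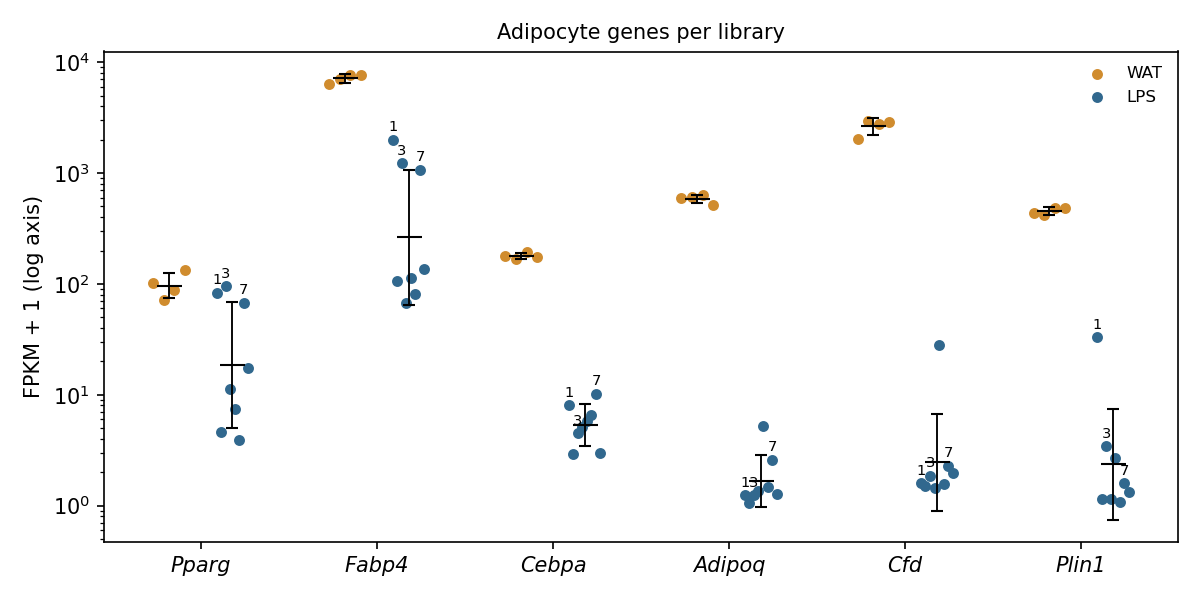
FPKM + 1 on a log axis of 6 adipocyte genes, 1 point per library, with the mean and SD of the log values per group, and LPS 1, 3 and 7 numbered. Pparg in those 3 tumours (66.5 to 94.2 FPKM) overlaps WAT (70.4 to 134 FPKM), while Adipoq is at most 4.26 FPKM in every tumour.

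Genes of fat metabolism fell with it. Of 15 fatty acid synthesis genes, 12 were lower and 1 higher (camera adjusted p = 1.54e-07; adjusted p = 0.149 with an estimated correlation): Fasn, the fatty acid synthase, fell from 1750 ± 550 to 29.2 ± 9.81 FPKM, Scd1 from 2527 to 11.3 FPKM, and Elovl5 stayed without a call (45.5 and 46.5 FPKM). Of 16 fatty acid oxidation genes, 15 were lower (camera adjusted p = 4.03e-13; adjusted p = 0.119 with an estimated correlation), led by Acsl1 at 618 and 7.44 FPKM. Of 13 brown and beige genes, 12 were lower and 1 higher (camera adjusted p = 1.08e-08; adjusted p = 0.0138 with an estimated correlation): Ucp1, the uncoupling protein that makes heat, fell from 562 ± 186 to 0.176 ± 0.0738 FPKM. The 1 higher member was not called without WAT 1, WAT 2 or WAT 3 (0 higher in each). All 26 nuclear genes of the respiratory chain were lower, with a median log2 difference of -1.99 (camera adjusted p = 7.77e-17; adjusted p = 0.119 with an estimated correlation), and Ndufa4 showed the steepest fall, from 564 to 15.8 FPKM. The 13 mitochondrially encoded genes lie in joined rows: the row of mt-Co1 held 16230 ± 3595 FPKM in WAT and 4100 ± 1124 FPKM in LPS, and the row of mt-Cytb 2599 and 475.5 FPKM. The row of mt-Nd1, at 48820 ± 17290 and 9866 ± 1893 FPKM, also holds the mitochondrial ribosomal RNAs, whose level depends on the depletion step. Cholesterol synthesis was mixed, with 7 of 17 lower, 1 higher (2 without LPS 1) and no call for the list (camera adjusted p = 0.534). Without WAT 1 and WAT 4, 4 were lower. Insig1, a brake on sterol synthesis, fell from 89.9 to 16.1 FPKM.

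Notch1 and most tested Notch target genes were higher in the tumours, while other genes of the pathway went both ways. Notch1 (chromosome 2, 26445696 to 26516663), whose row cannot part the receptor's own transcript from the transgene, measured 25, 29.9, 24.5 and 39.5 FPKM in WAT 1 to WAT 4 and 62.9, 84.6, 79.0, 55.5, 45.4, 79.6, 44.2 and 60.7 FPKM in LPS 1 to LPS 8. The means were 29.7 ± 6.98 and 64.0 ± 15.7 FPKM (SD, n = 4 and n = 8), a log2 difference of 1.07 ± 0.20 (limma adjusted p = 0.000703). Of 12 Notch target genes, 7 were higher and 2 lower (camera adjusted p = 0.0177; adjusted p = 0.277 with an estimated correlation), and adjusted over the list alone 8 were higher. The call of this list was lost after quantile normalization (adjusted p = 0.0570, the highest of a range from 0.00481 over alternatives). Heyl, a repressor that Notch switches on, rose from 7.22 ± 7.18 to 145 ± 52.3 FPKM, with WAT 4 at 18 FPKM against at most 3.99 FPKM in the other WAT libraries. Hey2 was also highest in WAT 4 within WAT, at 2.62 FPKM against at most 0.522 FPKM. Hey1 rose from 4.09 to 30.4 FPKM, Hey2 from 1.02 to 9.76 FPKM, Hes1 from 10.3 to 35.2 FPKM, Nrarp, a feedback inhibitor, from 10.4 to 63.5 FPKM, and the receptor gene Notch3 from 27.2 to 210 FPKM. Lfng and Dtx1 went the other way, at 20.6 and 5.62 FPKM and at 3.13 and 0.394 FPKM. Myc was not called (11.1 ± 2.02 and 10.5 ± 4.09 FPKM). Among 19 receptors, ligands and co-factors, 6 were higher and 5 lower, with no call for the list (camera adjusted p = 0.300). The lower count was 2 without WAT 2 and 3 without WAT 3, and without WAT 1 and WAT 4 3 were higher and 3 lower. In this list the ligand gene Jag1 rose from 14.3 to 56.6 FPKM, while Mfng, a sugar transferase that modifies Notch receptors, fell from 30.4 to 3.28 FPKM.

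Pericyte genes had the highest median log2 difference of the 40 lists tested. Of 11 tested pericyte and smooth muscle markers, 9 were higher, with a median log2 difference of 3.02 (camera adjusted p = 9.47e-08; adjusted p = 0.121 with an estimated correlation). Rgs5, a regulator of G protein signalling used as a pericyte marker (chromosome 1, 169655501 to 169695813), rose from 77.5 ± 7.99 FPKM in WAT (SD, n = 4) to 2957 ± 664 FPKM in LPS (SD, n = 8), 38.2-fold, and stood at rank 3 by mean among protein-coding genes in LPS against rank 585 in WAT. Actb stood at rank 5 in LPS. Kcnj8 and Abcc9, the neighbouring genes for both subunits of a potassium channel of pericytes, rose from 11.2 to 518 FPKM and from 20.1 to 515 FPKM, Cspg4 from 23.1 to 198 FPKM and Mcam from 46.4 to 195 FPKM. Pdgfrb, the pericyte and fibroblast receptor for platelet-derived growth factor, rose from 23.0 to 436 FPKM. Des, an intermediate filament gene of muscle, was not called (33.2 ± 19.5 and 25.6 ± 18.5 FPKM), nor was Acta2 (44.3 ± 3.76 and 64.6 ± 49.2 FPKM). Endothelial markers went mostly the other way, 10 of 15 lower and 2 higher (12 lower adjusted over the list alone), without a call for the list (camera adjusted p = 0.0740). It was called lower after quantile normalization (adjusted p = 0.0490) and without LPS 5 (adjusted p = 0.0342; highest over alternatives 0.105). Pecam1 fell from 58.6 to 26 FPKM and Kdr, the VEGF receptor, from 36.6 to 10.3 FPKM, while Emcn rose from 10.8 to 54.4 FPKM and Esam from 37.2 to 154 FPKM.

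**Figure D5:**
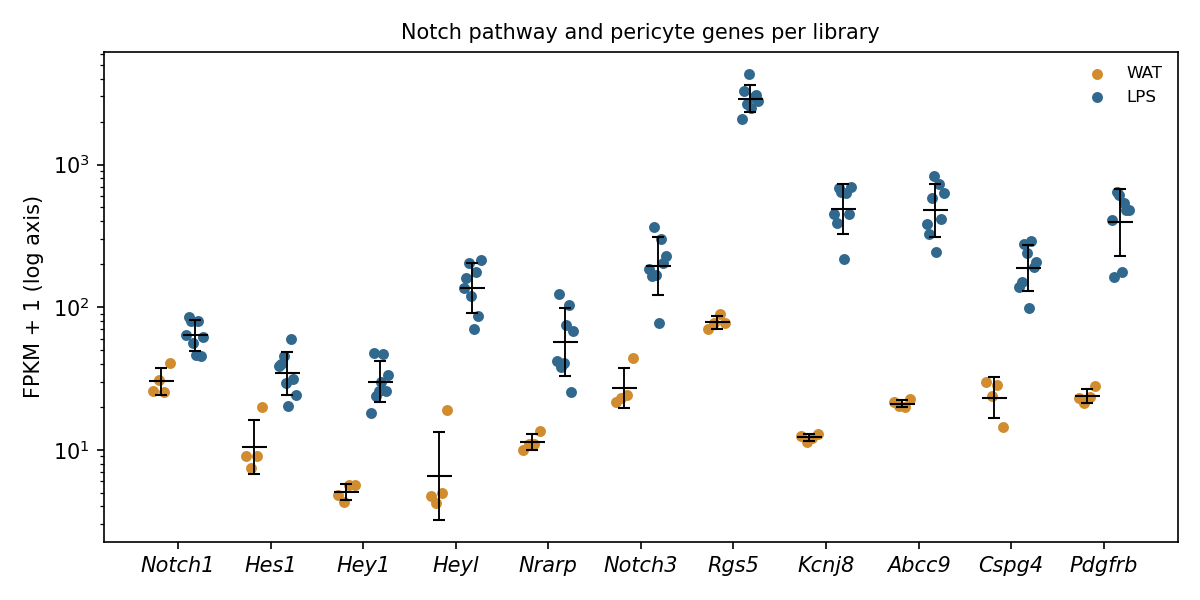
FPKM + 1 on a log axis of Notch pathway and pericyte genes, 1 point per library, with the mean and SD of the log values per group. For each gene the 8 LPS libraries lie above the 4 WAT libraries; Rgs5 runs from 69.2 to 88.4 FPKM in WAT and from 2068 to 4326 FPKM in LPS.

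Many proliferation genes were higher, with a count that moved with single libraries. Of 29 cell cycle genes, 18 were higher and none lower, and adjusted over the list alone 23 were higher (camera adjusted p = 1.36e-05; adjusted p = 0.617 with an estimated correlation). Cdk1, the kinase of mitotic entry, rose from 12.2 ± 5.58 to 49.7 ± 26.6 FPKM (SD, n = 4 and n = 8), with a limma adjusted p = 0.00339. Mki67 measured 9.37 ± 4.32 and 21.8 ± 8.85 FPKM (adjusted p = 0.0343). Leaving out WAT 3, WAT 4, LPS 2, LPS 4, LPS 5 or LPS 8 ended the call for Mki67 (limma adjusted p = 0.0751, 0.141, 0.0572, 0.0552, 0.0540 and 0.0560), and over the alternatives other than the test against a difference of 1 its adjusted p ran from 0.00408 to 0.268. Without WAT 4, 7 of the 29 cell cycle genes were higher, without WAT 3 12, and without WAT 1 and WAT 4 together 3. Without LPS 7, a tumour with 6.55 FPKM of Mki67, 24 were higher. Of 23 replication-dependent histone genes, which share reads among near-identical copies, 5 were higher, 0 adjusted over the list alone and 0 without WAT 1 and WAT 4 (camera adjusted p = 0.00330; adjusted p = 0.655 with an estimated correlation). That count of histone genes was 0 without WAT 3, 0 without WAT 4, 3 without LPS 2, LPS 5 or LPS 8, and 16 without LPS 7.

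Cell cycle inhibitors and tumour suppressors went both ways, 6 of 14 higher and 3 lower, 4 lower adjusted over the list alone (camera adjusted p = 0.312). Without WAT 1 and WAT 4, 3 were higher and 1 lower. Cdkn2a, which encodes p16INK4a and p19ARF (chromosome 4, 89274471 to 89294653), rose from 0.228 ± 0.186 FPKM in WAT to 39.9 ± 23.8 FPKM in LPS, with LPS 3 at 0.793 FPKM and the other 7 tumours between 11.4 and 73.0 FPKM. Trp53 rose from 15.3 to 23.3 FPKM (adjusted p = 0.00735, and 0.128 without WAT 1 and WAT 4, the highest of a range from 0.000609), while Cdkn2c fell from 92.9 to 14.2 FPKM. Of 11 genes amplified in human liposarcoma, 5 were higher (3 without WAT 2) and 1 lower (camera adjusted p = 0.0853). Cdk4 rose from 40.8 to 99.7 FPKM and Cpm from 2.85 to 16.6 FPKM, Mdm2 was not called (22.1 ± 1.51 and 27.8 ± 5.24 FPKM; adjusted p = 0.0955), and Hmga2 lay below the filter at 0 to 0.396 FPKM. Among 19 p53 target genes, 5 were higher and 5 lower, 6 and 6 adjusted over the list alone (camera adjusted p = 0.421). Fas, a death receptor, fell from 8.53 to 1.00 FPKM and Ddit4l rose from 1.88 to 11.8 FPKM, with WAT 4 at 3.90 FPKM and the other WAT libraries at 0.215 to 2.82 FPKM. For the p53 list camera pointed up and fry down.

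Basement membrane genes were more often higher than lower, and the other matrix lists went both ways without a call. Of 12 basement membrane genes, 6 were higher and 1 lower (camera adjusted p = 0.0197; adjusted p = 0.617 with an estimated correlation): Col18a1 rose from 31.3 to 242 FPKM and Col4a1, a chain of the main basement membrane collagen, from 338 ± 56.6 FPKM (SD, n = 4) to 1174 ± 421 FPKM (SD, n = 8). Without WAT 1 and WAT 4, 3 basement membrane genes were higher, and the 1 lower call was lost without WAT 1, WAT 2, WAT 3, LPS 2, LPS 4, LPS 5 or LPS 8 (0 lower in each). Of 23 fibrillar and structural matrix genes, 3 were higher and 8 lower, 5 lower without WAT 1 and WAT 4 (camera adjusted p = 0.726), with a median of 0.01 and a mean of -0.95: the small proteoglycan genes Dcn and Lum fell from 209 to 12.3 FPKM and from 63.1 to 4.46 FPKM, while Col6a3 rose from 154 to 652 FPKM. Among 19 remodelling enzymes, 6 were higher and 4 lower, 6 lower adjusted over the list alone and 7 lower without LPS 5 (camera adjusted p = 0.532). Mmp19, a matrix metalloproteinase, fell from 15.7 to 1.64 FPKM.

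Progenitor and mesenchymal genes divided. Of 19 adipocyte progenitor and fibroblast genes, 5 were higher and 8 lower, 9 lower adjusted over the list alone and 5 lower without WAT 1 and WAT 4 (camera adjusted p = 0.716). Dlk1, an inhibitor of fat cell differentiation, rose from 8.40 ± 3.57 to 173 ± 117 FPKM (SD, n = 4 and n = 8) and Cd248 from 19.6 to 125 FPKM, whereas Pi16 and Dpp4, markers of interstitial progenitors, fell from 30.7 to 1.62 FPKM and from 16.6 to 0.980 FPKM. LPS 5 held 5.60 FPKM of Pi16 and the other tumours 0.112 to 3.72 FPKM. Pdgfra, in a joined row, lay at 18.8 to 24.2 FPKM in WAT and 0.0765 to 3.42 FPKM in LPS. Of 15 epithelial-mesenchymal transition factors and mesenchymal markers, 9 were higher and 3 lower (camera adjusted p = 0.0213; adjusted p = 0.119 with an estimated correlation). Snai1 rose from 0.956 to 12.9 FPKM and Cdh2, N-cadherin, from 4.65 to 24.1 FPKM, while Vim was not called (336 ± 56.9 and 319 ± 84.3 FPKM). The lower count was 1 without WAT 2, WAT 3 or WAT 4. Without LPS 5 this list was not called (adjusted p = 0.0581; range over alternatives 0.0119 to 0.0581). Of 7 bone and cartilage genes, 3 were higher (camera adjusted p = 0.0712): Sp7, a factor of bone formation, rose from 0.0471 to 7.99 FPKM and Dmp1 from 0.0419 to 8.66 FPKM, with LPS 6 at 29.7 FPKM and the other tumours at 0.529 to 12.8 FPKM. Of 14 position and depot genes, 5 were higher and 1 lower (camera adjusted p = 0.0678). Nr2f1 rose from 2.97 to 53 FPKM, Hoxc8 fell from 10.6 to 2.54 FPKM, and Hoxc13 was listed at 0 in the 4 WAT libraries and averaged 2.76 FPKM in LPS. The position list passed without WAT 4 (adjusted p = 0.0405) and without LPS 1 (adjusted p = 0.0406), in a range over alternatives from 0.0236 to 0.122.

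Interferon genes were higher, T and B cell genes were lower, and macrophage genes went both ways. Of 19 type I interferon response genes, 17 were higher (camera adjusted p = 2.50e-06; adjusted p = 0.529 with an estimated correlation): Ifi44 rose from 1.58 ± 0.399 to 36.4 ± 18.7 FPKM (SD, n = 4 and n = 8) and Oasl2, of the oligoadenylate synthetase family, from 5.75 to 45.1 FPKM. Of 17 macrophage markers, 8 were higher and 2 lower (camera adjusted p = 0.0378; adjusted p = 0.655 with an estimated correlation), and 1 was higher without WAT 1 and WAT 4. Leaving out WAT 1, LPS 1, LPS 5, LPS 6 or LPS 7 ended the call of the macrophage list (adjusted p = 0.0532, 0.0501, 0.0841, 0.0533 and 0.0549). So did quantile normalization (adjusted p = 0.105) and leaving out WAT 1 and WAT 4 (adjusted p = 0.0778), in a range over alternatives from 0.00985 to 0.147. Fcgr1, a high-affinity IgG receptor, rose from 1.05 to 7.93 FPKM, and Cd163, a scavenger receptor of resident macrophages, fell from 10.8 to 2.13 FPKM. Of 17 cytokines and chemokines, 7 were higher and 3 lower, or 3 and 1 without WAT 1 and WAT 4 (camera adjusted p = 0.0853). Il1b rose from 0.390 to 7.78 FPKM and Ccl5, a T cell attractant, fell from 34.3 to 5.43 FPKM (20.8 FPKM in LPS 1 and at most 6.31 FPKM in the other tumours), and without LPS 8 the list passed (adjusted p = 0.0486; range over alternatives 0.0486 to 0.193). Of 13 antigen presentation genes, 4 were higher and 1 lower (camera adjusted p = 0.105): Psmb8, of the immunoproteasome, rose from 53.4 to 130 FPKM. Without WAT 1 and WAT 4, 0 of these genes were called either way, and Psmb8 had an adjusted p of 0.0514 (limma, the highest of a range from 8.92e-05). The 1 lower antigen presentation call was lost without WAT 2 (0 lower), and 2 were lower without LPS 1, LPS 6 or LPS 7.

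Of 14 T and NK cell markers, 10 were lower, and adjusted over the list alone 11 were lower and 1 higher (camera adjusted p = 0.000775; adjusted p = 0.617 with an estimated correlation). Over all rows 1 was higher without LPS 4, LPS 5 or LPS 8, against 0 with all libraries. Of 13 B cell and lymph node markers, 12 were lower (camera adjusted p = 1.99e-08; adjusted p = 0.201 with an estimated correlation). Cd3g, of the T cell receptor complex, fell from 21 ± 5.86 to 1.29 ± 2.03 FPKM (SD, n = 4 and n = 8), Ms4a1, the B cell antigen CD20, from 15.8 to 0.103 FPKM, and Ccl21a, a lymph node chemokine, from 55.1 to 0.324 FPKM. LPS 1 held 6.14 FPKM of Cd3g, against at most 1.27 FPKM in the other tumours, and LPS 5 held 1.93 FPKM of Ccl21a, against at most 0.467 FPKM. WAT 2 held more Cd3g than the other WAT libraries, 29.8 FPKM against 17.9 to 18.2 FPKM. Among 8 plasma cell markers, 3 were higher and 1 lower, 4 higher adjusted over the list alone and 5 higher without LPS 5, with 2 lower without LPS 1 (camera adjusted p = 0.151): Sdc1, also made by other cells, rose from 5.28 to 39.2 FPKM and Mzb1 fell from 3.94 to 0.476 FPKM. Of 9 neutrophil and mast cell markers, 1 was higher and 2 lower, and none adjusted over the list alone (camera adjusted p = 0.716). The lower count was 0 without WAT 1 or WAT 4, 1 without WAT 2, WAT 3, LPS 1, LPS 2, LPS 3, LPS 4 or LPS 7, and 4 without LPS 8. The higher call was lost (0 higher) without WAT 1, WAT 2, WAT 3, WAT 4, LPS 1, LPS 6 or LPS 7.

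Nerve markers were far lower in the tumours. Of 12 nerve and Schwann cell markers, 11 were lower and 1 higher (camera adjusted p = 7.58e-06; adjusted p = 0.119 with an estimated correlation). The myelin gene Mbp fell from 51.9 ± 5.52 to 1.41 ± 1.04 FPKM (SD, n = 4 and n = 8), and Ngfr rose from 2.67 to 35.1 FPKM. The call for Ngfr ended without WAT 1 and WAT 4 (limma adjusted p = 0.0747, the highest of a range from 0.00172), and 0 members of the list were higher. Skeletal muscle transcripts varied within WAT: Ttn measured 178, 0.967, 23.1 and 166 FPKM in WAT 1 to WAT 4. Of 16 muscle markers, 5 were lower, 1 adjusted over the list alone (camera adjusted p = 0.0549). The count depended on nearly every library: 1 without WAT 1 or WAT 4, 2 without WAT 3, LPS 2, LPS 3, LPS 5, LPS 6 or LPS 7, 3 without LPS 4, 13 without LPS 8 and 15 without WAT 2. That list passed on leaving out WAT 2, WAT 3, LPS 1, LPS 4 or LPS 8 (adjusted p = 0.000531, 0.0496, 0.0453, 0.0414 and 0.00982), and after quantile normalization (adjusted p = 0.0210), and its range over alternatives ran to 0.885. Of 7 erythroid and blood genes, 6 were lower, but 3 without WAT 2, WAT 3, WAT 4, LPS 1, LPS 2, LPS 7 or LPS 8 (camera adjusted p = 0.112), and without LPS 5 the list passed (adjusted p = 0.0187; highest over alternatives 0.168). All 18 epithelial and 10 mesothelial markers lay below the filter. Krt19 averaged 2.21 FPKM in WAT and 0.0806 FPKM in LPS, and Upk1b reached 8.00 FPKM in LPS 7.

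Hypoxia, glycolysis and growth factor genes changed member by member. Of 16 angiogenic and hypoxia genes, 7 were higher and 2 lower, 4 lower adjusted over the list alone (camera adjusted p = 0.178): Ankrd37 rose from 2.50 to 36.4 FPKM, whereas Vegfa, the main vessel growth factor, fell from 92.2 ± 3.83 to 17.1 ± 13.2 FPKM and Bnip3 from 137 to 15.6 FPKM. Of 18 glycolysis genes, 3 were higher and 9 lower (camera adjusted p = 0.272): hexokinase genes parted, Hk1 rising from 11.4 to 41.9 FPKM and Hk2 falling from 47.9 to 3.21 FPKM. Of 16 receptor kinase and growth factor genes, 2 were higher and 6 lower, 7 lower adjusted over the list alone (camera adjusted p = 0.252). Fgf10 fell from 10.5 FPKM to at most 0.165 FPKM in each tumour, Met from 13.8 to 1.16 FPKM, and Pdgfa, a ligand of platelet-derived growth factor receptors, rose from 5.03 to 20.3 FPKM. Of 14 imprinted genes of the postnatal growth programme, which is silenced with age, 7 were lower and 1 higher, with 2 higher without LPS 1, LPS 5 or LPS 7 (camera adjusted p = 0.104). Peg3 fell from 46.8 to 0.428 FPKM, Nnat from 299 to 3.88 FPKM and Igf2 from 23.1 to 2.25 FPKM (9.76 FPKM in LPS 2 and at most 3.61 FPKM in the other tumours), and the joined row of H19 lay at 144 to 277 FPKM in WAT and 0.645 to 75.7 FPKM in LPS. The joined rows of Meg3, Rian and Mirg, which lie in 1 imprinted cluster, had higher means in LPS with a wide spread: 53.9 ± 18.1 and 326 ± 290 FPKM, 89 ± 35.8 and 685 ± 618 FPKM, and 10.2 ± 5.50 and 123 ± 151 FPKM (SD, n = 4 and n = 8). In these rows LPS 3 lay below every WAT library, at 3.56, 5.08 and 0.561 FPKM, and LPS 7 lay within the WAT range. Of 14 unfolded protein response genes, 3 were higher (5 without LPS 5) and 4 lower (2 without WAT 3; camera adjusted p = 0.418; median 0.19, mean -1.73e-04), Asns falling from 31.3 to 10.4 FPKM. Of 12 stemness factors, 4 were higher and 4 lower: Sox4 rose from 5.54 to 32.2 FPKM and Klf4 fell from 14.0 to 1.47 FPKM, with a median of -0.29 and a camera direction of up (adjusted p = 0.874). Of 15 immediate early genes, which handling can raise, 2 were higher and 1 lower (camera adjusted p = 0.259), with 1 higher without WAT 1, WAT 3 or WAT 4, 4 without LPS 1, 5 without LPS 8, and 2 lower without LPS 6 or LPS 7. The 4 tested sex-linked genes were not called.

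No gene passed a test for a trend across tumours with the age of the animal, between 9 and 12 months. limma called 0 of 13280 rows for a slope per month, 228 had an unadjusted p below 0.05, and the smallest adjusted p was 0.109. Notch1 had a slope of -0.26 ± 0.10 per month, Pparg of 0.70 ± 0.55 and Mki67 of -0.21 ± 0.22 (SE, 8 tumours; limma adjusted p = 1.00 for each).

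Tumours differed from one another more than fat samples did. The median SD of log2(FPKM + 1) was 0.347 over the 8 LPS libraries and 0.165 over the 4 WAT libraries, a ratio of 2.1, and over all 70 sets of 4 LPS libraries the ratio ran from 1.63 to 2.25. Within LPS the cell cycle score followed the score of replication-dependent histones, with Pearson r = 0.935 (exact permutation p = 0.00117, adjusted p = 0.00816 over 7 relations) and Spearman rho = 0.833 (exact permutation p = 0.0154, adjusted p = 0.0538). Without LPS 7 and LPS 2, the libraries farthest from the median, r was 0.921. Notch1 and the Notch target score gave r = 0.752 (exact permutation p = 0.0307, adjusted p = 0.0716) and rho = 0.833 (exact permutation p = 0.0154, adjusted p = 0.0538), and r = 0.722 without LPS 7 and LPS 2, short of the threshold after adjustment; Notch1 is not itself on that list. The mature adipocyte score followed the structural matrix score by Pearson r = 0.777 (exact permutation p = 0.0123, adjusted p = 0.0429), but not by Spearman rho = 0.714 after adjustment (exact permutation p = 0.0576, adjusted p = 0.101). Without LPS 2 and LPS 5 this r was 0.659, and after quantile normalization r = 0.790 no longer passed. With the Notch target, cell cycle, macrophage and progenitor scores the mature adipocyte score gave r = -0.542, -0.482, 0.692 and 0.481 (adjusted exact permutation p = 0.233, 0.233, 0.0957 and 0.233). Their rho values were -0.357, -0.381, 0.714 and 0.524 (adjusted exact permutation p = 0.389, 0.389, 0.101 and 0.275), and none passed. The mature adipocyte score lay between -0.55 and -0.17 in 4 tumours and between 0.17 and 0.48 in the other 4, a gap of 0.330 of its range, so clusters are not excluded and these relations are uncertain. This score was highest in LPS 5 (0.477), the library that stood apart in Gm10800 and receptor genes. Apart from Pparg, the median share of the WAT mean over its genes was 0.00163 to 0.00832 per tumour. It thus ranks mostly small remnants of these transcripts.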

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

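The tests of the patterns weighed in this part were chosen only after the result was seen, except the splits of the libraries, which were planned. A library was singled out where its gap to the nearest other library of its group was a large share of the group's range by Dixon's test at 95%. Of 360 gene groups tested, 32 (8.90%) held such a library, and chance gives about 5%. Of 12 groups of library measures, 5 did.

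LPS 5 had 23644 rows above 0, against at most 21105 in other tumours (2.36e+04 when rounded). In LPS 5, 754 of 1408 olfactory and vomeronasal receptor genes, which are hardly expressed outside sensory tissue, were above 0, Gm10800 stood at 3.62e+05 FPKM, and the 10 highest rows took 63.7% of the FPKM sum against 43.4% to 50.9% in the other tumours. Greater depth is argued against, because 9 libraries had a smaller one-fragment step than LPS 5 and at most 160 such genes above 0. Whether genomic DNA in the library is the source was not decided, since the count of 754 receptor genes is the observation itself and no independent test was run. No biological explanation was tested.

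Pparg stood near its WAT level in LPS 1, LPS 3 and LPS 7, at 0.836, 0.959 and 0.676 of the WAT mean. Residual normal adipocytes are argued against: the other 28 mature adipocyte genes kept a median share of at most 0.00832 of their WAT mean in these libraries. Of those genes, Fabp4 (0.278, 0.171 and 0.149) and Cd36 (0.123, 0.125 and 0.0669) kept larger shares in LPS 1, LPS 3 and LPS 7 than in the other tumours, while Slc2a4 (0.319, 0.604 and 0.933) and Tusc5 (0.477, 0.588 and 0.514) had shares in LPS 4 (0.320 and 0.523) and LPS 8 (0.367 and 0.504) above those in LPS 1. Sex is argued against too, since the Y-linked Eif2s3y was above 1 FPKM in 1 of these 3 libraries and in 2 of the other 5 tumours. Other differences between the tumours, body site among them, were not tested and stay open.

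The 9 called pericyte and smooth muscle markers invite the question of which cells carry them. More vessels of every kind are argued against by the endothelial list, which had a median log2 difference of -1.24. Its SE of 0.219 came from resampling the member genes as if independent, not the animals. Of its 15 members 10 were lower and 2 higher, and the list was not called (camera adjusted p = 0.0740). Loss of adipocyte RNA as the only change would raise all other cell types alike, and is argued against because other cell types moved apart. All 4 lists chosen for this lay below 0 (endothelial at -1.24, nerve at -2.02, T and NK cells at -2.77, B cells at -3.48). Macrophage and plasma cell markers lay at 0.94 and 1.45, and pericyte markers at 3.02 (SE 1.26, over member genes). Such a loss beside other changes in cell content was not tested and stays open. Tumour cells that express mural genes and an excess of pericytes cannot be told apart, since bulk RNA with Rgs5 at rank 3 in LPS allows both. Age differs between the groups as well and stays open.

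The gene comparison was set against 100 splits of the 12 libraries into 4 and 8. Only 1 of the 100, the real one, called as many as 6813 genes, and the highest other called 50. This argues against chance, with 1 in 100 the smallest share that these splits can give. It does not bear on age, which differs between the groups. For the list tests, 36 of the 100 splits called at least 16 lists and the highest other called 27. Part of the difference between LPS and WAT stays in the splits, so they cannot decide whether the number of lists exceeds chance.

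Among WAT libraries, WAT 4 stood apart in Heyl at 18 FPKM (others 3.20 to 3.99), Notch3 at 42.8 (20.7 to 23.2), Mfng at 18.5 (32.4 to 35.8), Lyve1 at 8.91 (16.2 to 16.4) and Sox4 at 7.23 (4.86 to 5.18). WAT 2 stood apart in Ciita at 13.7 FPKM (others 6.02 to 6.16), Cd3g at 29.8 (17.9 to 18.2), Cxcl13 at 21.4 (5.55 to 6.56), Trp53 at 19.3 (13.9 to 14.1), Pdgfa at 6.21 (4.53 to 4.70), Bgn at 51.5 (54.3 to 54.7), Vegfa at 86.5 (93.7 to 94.9) and Snai1 at 0.601 (1.04 to 1.13). WAT 1 had Cfd at 2.05e+03 FPKM (others 2800 to 2923) and Eif2s3y at 46.8 (others at most 0.0303).

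Among tumours, LPS 7 stood apart in Cxcl13 at 120 FPKM (others at most 7.74), Sdc1 at 116 (19.7 to 41.5), Cd4 at 48.2 (0.996 to 6.01) and Klf4 at 4.70 (0.386 to 1.70). LPS 5 stood apart in Cfd at 27.2 FPKM (0.450 to 1.29), Ebf2 at 14.1 (30.7 to 58.4), Apc at 18.6 (25.3 to 30.7), Marco at 0.424 (at most 0.0476) and Ccl21a at 1.93 (at most 0.467). These values were not rescaled for the low median ratio of LPS 5 (0.814), which bears on its low Ebf2 and Apc. LPS 3 was low in Col15a1 at 18.2 FPKM (117 to 547). LPS 1 was high in Plin1 at 32.2 FPKM (0.0831 to 2.41) and Cd3g at 6.14 (at most 1.27), and its one-fragment step was 0.0896 (0.0424 to 0.0647). LPS 8 was high in Cox8b at 12.6 FPKM (0.292 to 2.29) and Cma1 at 33.3 (0.750 to 5.89), LPS 4 low in Mfng at 0.967 (2.58 to 4.43), and LPS 6 high in Junb at 296 (10.0 to 47.0).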

How the results depend on the processing

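The alternatives without joined and small RNA rows and without the muscle-rich WAT libraries were chosen only after the data were seen, and the others were planned. Calls numbered 6813 (2806 higher, 4007 lower). With a mean FPKM of at least 5 they were 4506 (2468 lower), because fewer rows were tested (9894). Against a log2 difference of 1 they were 1595 (433 higher, 1162 lower), by that test's construction. Without WAT 1 and WAT 4 they were 4319 (1462 higher), with fewer samples. Without LPS 5 as well they rose to 4816 (1845 higher), and the cause of this rise was not tested. Leaving out 1 library gave 5701 to 7208 calls, 2219 to 3218 higher and 3482 to 4057 lower. The list tests gave 15 to 18 calls on leaving out 1 library and 2 with an estimated correlation. Of 7 relations between scores 2 passed, and 1 after quantile normalization (the cause was not tested). The first component held 55.9% with pseudocount 0.1, against 59.0% (the cause was not tested). The age slope called 0 rows in limma with pseudocount 0.1, with no filter and without each LPS library, the alternatives run for it. Of 5023 comparisons of named genes with alternatives, 4741 kept direction and side of the threshold, 248 lost the call, 34 gained it and 0 reversed; of 680 for lists the numbers were 636, 25, 19 and 0. Without WAT 1 and WAT 4, further list counts moved, of which some are given here. Higher calls went to 0 for fatty acid synthesis, thermogenic, neutrophil and mast cell and immediate early genes. They went to 1 for unfolded protein response and growth factor genes, 5 for angiogenic and hypoxia genes and 14 for interferon genes. Lower calls went to 0 for skeletal muscle and neutrophil and mast cell markers, 1 for epithelial-mesenchymal genes and 3 for erythroid genes. They went to 5 for imprinted genes, 6 for glycolysis genes and 7 for endothelial markers. With the replicate block 6039 rows were called, but equal numbers did not pair the samples: deviations of same-numbered libraries correlated by -0.017, 0.0175, 0.0921 and 0.0332, and only number 3 was its own best match. By one-fragment steps LPS 1 was the shallowest library.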

Other observations

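The genes and tests of this part were chosen only after the result was seen. Some genes outside the lists, picked for their large differences, separated tumours from fat. Casq2, a calcium store protein of muscle, averaged 3.73 FPKM in WAT and 126 FPKM in LPS, and Gja4, a connexin, 5.71 and 166 FPKM. The receptor genes S1pr3 and Ednra averaged 6.11 and 166 FPKM and 6.04 and 95.6 FPKM. The transcription factor genes Tbx2 and Foxs1 rose from 4.58 to 111 FPKM and from 5.05 to 77.9 FPKM (limma, log2 difference 4.31 ± 0.21 and 3.66 ± 0.24, SE). WAT 1 held 7.98 FPKM of Casq2 (0.497 to 4.99 FPKM in the other WAT libraries) and WAT 4 held 12.5 FPKM of Ednra (3.55 to 4.38 FPKM). For each of these genes all 8 tumours lay above all 4 WAT libraries.

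LPS 1, LPS 3 and LPS 7, which lie apart on the second principal component, also held several transcripts, picked for this pattern, that were low in the other tumours. Id4, an inhibitor of helix-loop-helix factors, measured 66.4, 122 and 85 FPKM in them and 0.149 to 1.27 FPKM in the other 5. Gipr, an incretin receptor, measured 57.6, 74.6 and 12.3 FPKM, against 1.00 to 2.88 FPKM in the others, and Gcgr, the glucagon receptor, 26.1, 41.9 and 13.9 FPKM, against 0.0299 to 2.64 FPKM. Timp4, a protease inhibitor, measured 65.3, 74.9 and 97.9 FPKM, against at most 1.43 FPKM. Tbx5, on the position and depot list but below the filter, measured 11.4, 24.2 and 3.26 FPKM, against at most 0.142 FPKM. No test was run on these libraries as a group.

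The Y-linked genes Eif2s3y and Ddx3y were above 1 FPKM in WAT 1, LPS 1, LPS 6 and LPS 8, at 46.8, 43.7, 7.40 and 43.5 FPKM for Eif2s3y and 27.3, 32.4, 34.4 and 2.72 FPKM for Ddx3y. Xist, in a joined row, measured 0.0755 FPKM in WAT 1, 3.74 in LPS 1, 0.660 in LPS 6 and 17 in LPS 8, and 44.4 to 188 FPKM in the other 8 libraries.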
